A study of Mus musculus with 20 samples.

How the data were processed

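RNA from mouse cells was measured on 20 one-colour Agilent arrays in 10 groups of 2. Per the file headers, the scanner files hold the processed signal of each spot as an intensity, after spatial and multiplicative detrending by Agilent's extraction software and with surrogate values for dim spots, and they are not normalized between arrays. The deposited value table holds log2 values with a column for each array and no stated normalization or centring; its column medians lay between 5.794 and 6.28. Probe coordinates in the scanner files are on the mouse build mm9. Every per-sample column was matched to a sample, so 0 were unmatched.

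The comparisons were computed from the scanner files. Each array's log2 processed signal was set relative to that array's 75th percentile over the non-control spots, and all levels printed are on this scale. Spots marked as outliers by the extraction software were left out, and the spots of a probe were averaged. A probe was kept if it was well above background on both arrays of at least 1 of the 10 groups, and each gene was represented by its probe with the highest mean over the 20 arrays. This left 25402 genes. The arrays carried 55681 non-control probes, of which 28830 had a RefSeq accession; 27428 of these matched the supplied table of symbols, which updated 2788 names. No genome sequence was used here, and probes were not realigned.

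A linear model with 1 mean per group was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 with the data.table package at version 1.17.8, with moderated variances, and p-values were adjusted over the genes tested by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, and the number of called genes at 2-fold or more is given beside each count. A standard error (SE) of a log2 difference comes from this fit, and an SD is between the 2 arrays of a group. Where a gene was not well above background on either array of a group, with any of its probes, its fold difference against that group is given only as a lower bound, computed against that group's background limit. Some list medians are also given with such members at their bound. Genes well above background on only 1 of the 2 arrays of a group are called partly detected.

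A set of 25 gene lists with 556 genes was fixed before the data were examined, as were the comparisons, the test, the rule for the genes named and most alternatives. Lists were tested within each comparison with limma's camera at its preset correlation between genes of 0.01, and the p from a correlation estimated within each list is given beside it. For members of a called list, the number called after adjustment over the list alone is given where it differs from the number called over all genes. The genes named in each comparison are the 6 largest rises and 6 largest falls among genes well above background on all arrays compared, called, with non-overlapping groups and a proper symbol; Cebpa, Klf4, Pou5f1, Sox2, Myc, Nanog, Kdm1a, Brd4 and Tet2 in the B cell and pluripotent comparisons; up to 4 members with the smallest adjusted p of each list described; and the pluripotency and B lineage genes by the first stage at which they were detected. Any other gene named was chosen after its values were seen, and the text says so.

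Groups follow the source names of the samples. For the granulocyte-macrophage progenitor (GMP) arrays the titles give other groups: the arrays named slow by source are titled as the total population, and those named total by source are titled slow. The GMP columns of the value table matched other arrays better than their own (r across 29101 probes 0.9957 to 0.998, against 0.9813 to 0.9898 with their own array).

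The tests were tried on data simulated from these arrays. Over 10 comparisons, 7.5 to 17.9% of seeded 1.5-fold, 34.3 to 47.8% of 2-fold and 62.1 to 84.8% of 4-fold changes were recovered. With 200 seeded changes, 3 to 7 unchanged genes were called. A list shifted by 0.5 was called in all 10 comparisons and no other was. This did not test the preset correlation. The number of arrays limits precision, and no depth applies to arrays.

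Alternatives changed the normalization (quantile, background-corrected quantile, array median), the source of the values (value table), the filter on dim probes, the probe rule, the arrays in the fit, the block (replicate number or slide), the variance prior and the grouping of the GMP arrays, and left out each array in turn. When an array was left out, the remaining array of its group was assumed to vary like the other groups. The slide of each array was read from the scanner output. Replicate numbers were not used as pairs. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The 140 control probes of the value table were left out.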

Results

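The series measured messenger RNA in mouse cells on their way from pre-B cells to pluripotent cells, and in myeloid progenitors. Arrays were made from CD19+ pre-B cells of bone marrow grown with IL-7 (B cells), from the same kind of cells after an 18 h pulse of the myeloid transcription factor C/EBPa (pulsed cells), and from Oct4+ cells sorted 1, 2 and 3 days after the reprogramming factors Oct4, Klf4, Sox2 and Myc (OKSM) were induced. C/EBPa was activated with 100 nM estradiol on a layer of fibroblast feeder cells, and OKSM with 2 µg/ml doxycycline. Feeder cells were removed by pre-plating before RNA was taken. The other groups were induced pluripotent stem (iPS) cells, embryonic stem (ES) cells of the E14TG2 line, and granulocyte-macrophage progenitors (GMPs) sorted as fast dividing, slow dividing or total. Each of the 10 groups had 2 arrays, so n = 2 holds for every group mean below. The titles number the pair as biological replicates, with no word on whether they came from separate cultures or animals. GMP groups are called here by their source names, and the titles exchange slow and total.

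Every array had 62976 spots, of which 59305 were not controls. The share of these well above background ran from 44.2% in fast GMP replicate 1 to 61.8% in B cell replicate 1, and the 75th percentile of the signal from 463 in fast GMP replicate 1 to 1565 in iPS replicate 1. Replicates correlated at r = 0.9732 across genes on day 3 and at 0.9864 to 0.9945 in the other 9 groups. The first principal component took 38.9% of the variance and the second 27.7%. The B cell series lay on a pair of slides, each with 1 array per group, while iPS cells, ES cells and GMPs each had a slide of their own. Slide and cell type thus cannot be separated in comparisons across these, while the GMP groups shared 1 slide.

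**Figure D1:**
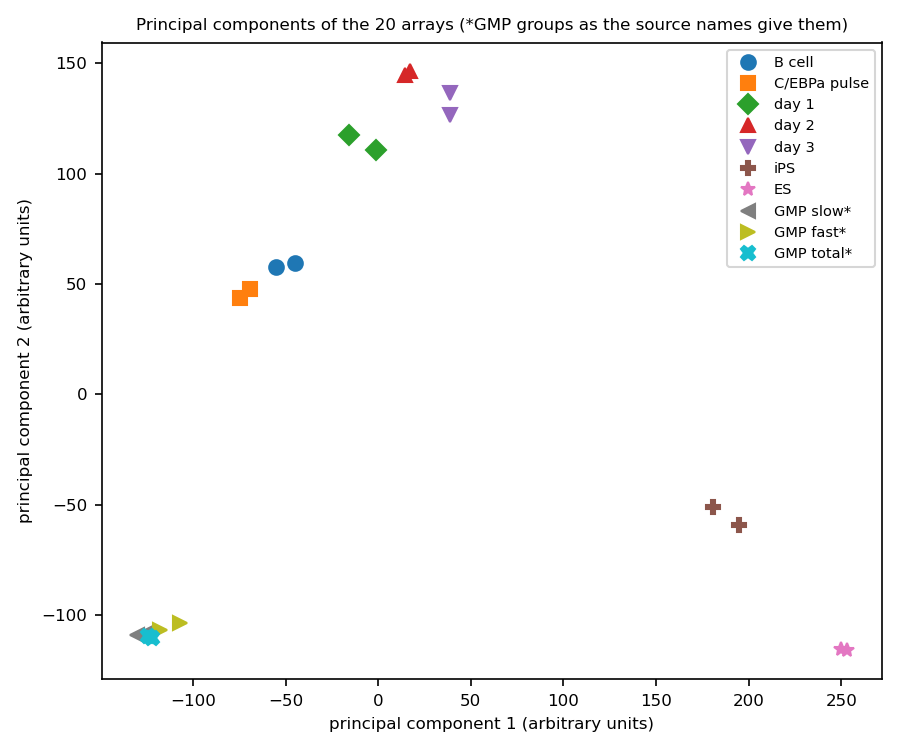
Each point is 1 array on the first principal component (horizontal axis, 38.9% of the variance) and the second (vertical axis, 27.7%), both in arbitrary units, coloured and shaped by group. GMP groups are as named by source. Replicates lie close together. IPS replicate 1 lies at 180.82 on the first component and both pulsed arrays at -69.29 and -74.43.

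The first comparison asked what the C/EBPa pulse did to pre-B cells. Most macrophage and granulocyte granule genes rose, and most B lineage and cell cycle genes and 6 of 12 class II antigen presentation genes fell. Of these list calls, those for B lineage and granule genes held with an estimated correlation. The largest rises were Hp, the plasma haemoglobin carrier haptoglobin, at 1950-fold (log2 10.93, SE 0.974), the neutrophil collagenase Mmp8 at 1490-fold, the apolipoprotein gene Apoc1 at 1240-fold, the granule protease Prtn3 at 777-fold, Pi16 at 767-fold and the chemokine receptor Ccr5 at 426-fold (adjusted p 6.32e-09 to 0.000101). The largest falls were smaller: the cytokine gene Lta was 10.6-fold lower (SE 0.381), Rd3l 9.62-fold, Capsl 9.26-fold, the lymphocyte signalling gene Sit1 8.93-fold, the pre-B cell surface peptidase Enpep 8.91-fold and Heyl 8.91-fold lower. Heyl's call was lost without any 1 of the 4 arrays.

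Of 27 B lineage genes 20 fell, none rose and 7 did not pass (22 adjusted over the list alone), with a median of -1.78 (camera adjusted p = 2.17e-13, adjusted p = 0.00865 with an estimated correlation). Dntt, which adds nucleotides during immunoglobulin gene rearrangement, was 7.75-fold lower, the receptor for IL-7 (Il7r) 4.81-fold, the B cell adaptor Blnk 3.38-fold and Foxo1 3.22-fold lower. Among 28 macrophage genes 19 rose and none fell (median 2.08, adjusted p = 3.54e-15; adjusted p = 0.122 with an estimated correlation), among them the phagocyte oxidase subunit Cybb at 21.7-fold, the signalling adaptor Tyrobp at 68.4-fold, the Fc receptor Fcgr3 at 10.5-fold and Il1b at least 174-fold. Granule genes of granulocytes rose in 13 of 22 and fell in none (median 2.06, or 1.83 with bounds, adjusted p = 1.25e-09; adjusted p = 0.00865 with an estimated correlation), with Fcnb 49.1-fold, Elane 12.2-fold, Camp 14.4-fold and Ctsg 422-fold higher. The medians on the 2 slides were -1.87 and -1.75 for B lineage, 2.14 and 2.02 for macrophage and 2.75 and 1.98 for granule genes.

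Genes of the G2 and M phases fell in 23 of 25 (24 over the list alone, median -0.90, adjusted p = 2.39e-17; adjusted p = 0.0692 with an estimated correlation), such as the mitotic regulators Cdc20, 2.06-fold lower, and Plk1, 1.94-fold lower. S phase genes fell in 20 of 25 (21 over the list alone, median -0.68, adjusted p = 1.47e-12; adjusted p = 0.0513 with an estimated correlation), including Uhrf1, 2.18-fold lower, and Rrm1, a subunit of ribonucleotide reductase, 2.02-fold lower. Glycolysis genes rose in 12 of 18 (13 over the list alone, median 0.79, adjusted p = 1.37e-10; adjusted p = 0.0608 with an estimated correlation), with hexokinase Hk2 4.69-fold and the glucose transporter Slc2a3 4.42-fold higher. In the immediate early and stress list 9 of 17 rose and 1 fell (10 over the list alone, median 1.09, adjusted p = 6.22e-06; adjusted p = 0.136 with an estimated correlation), with Fos 14.3-fold and Atf3 10.6-fold higher. Class II antigen presentation genes fell in 6 of 12 and rose in 1 (median -1.41, adjusted p = 0.0101; adjusted p = 0.0949 with an estimated correlation): the invariant chain Cd74 was 4.67-fold lower and H2-Ob 3.5-fold lower, while the costimulator Cd86 was 14.5-fold higher. T and NK cell genes fell in 6 of 16, such as the kinases Lck, 6.5-fold lower, and Zap70, 6.37-fold lower (median -0.35, adjusted p = 0.0101; adjusted p = 0.164 with an estimated correlation).

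Chromatin regulators fell in 7 of 27 and rose in 2 (10 changed over the list alone, median -0.23, adjusted p = 0.0101; adjusted p = 0.701 with an estimated correlation). The histone methyltransferase Ezh2 was 2.5-fold and the remodeller Smarca4 2.26-fold lower. Interferon genes rose in 5 of 23 and fell in 2 (median 0.18, adjusted p = 0.0333), and ribosome biogenesis genes fell in 1 of 24, Odc1 of polyamine synthesis, 1.32-fold lower (median -0.22, adjusted p = 0.0412, no member passed over the list alone). Both lists had an adjusted p = 0.748 with an estimated correlation. These 3 list calls hung on single arrays. The interferon call was lost without pulsed replicate 1 or B cell replicate 2. The ribosome call was lost without pulsed replicate 1 or B cell replicate 1, and the chromatin call without B cell replicate 1.

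The remaining 13 lists were not called (adjusted p 0.0513 to 0.645). Of the stem and progenitor genes 7 rose and 3 fell of 22, of the pluripotency genes 2 rose and 1 fell of 30, and of the 26 feeder and fibroblast genes none changed. Oxidative phosphorylation genes were called without B cell replicate 2 (adjusted p = 0.043). Median and mean differed in sign for p53 target genes (-0.07 and 0.13), DNA methylation genes (-0.01 and 0.01) and megakaryocyte genes (0.13 and -0.47).

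Among the single genes of interest, Klf4, a reprogramming factor also expressed in myeloid cells, rose 4.52-fold (log2 2.18, SE 0.449, adjusted p = 0.00442), from 0.47 ± 0.22 to 2.65 ± 0.04 (SD, n = 2). Tet2, an enzyme that oxidises methylated cytosine, rose 1.96-fold (adjusted p = 0.00514), while Tet1 was 2.24-fold lower. The histone demethylase Kdm1a (log2 -0.41, adjusted p = 0.0716), the bromodomain gene Brd4 (-0.18, 0.672), Myc (0.28, 0.628) and Nanog (0.24, 0.814) did not pass. The Cebpa probe was detected on 1 array of each group (log2 difference 0.04, adjusted p = 0.982), and Pou5f1 and Sox2 were below background in both. Whether the probes for Cebpa, Pou5f1, Sox2, Klf4 and Myc also detect the induced transcripts was not settled. The Nanog probe used read -3.15 and -2.93 on the ES cell arrays, where the other Nanog probes read 3.65 and 3.73, and 6.77 and 6.82.

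In all, 4848 of 25402 genes were called, 2255 higher and 2593 lower in pulsed cells, 2390 of them at 2-fold or more. With the slide as a block 6130 were called, and the differences on the 2 slides correlated across genes at r = 0.846. The count was 3159 without pulsed replicate 1, 3027 without pulsed replicate 2 and 2949 without B cell replicate 1.

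The step from pulsed cells to day 1 asked what OKSM and the Oct4+ sort changed. Most macrophage, granule and B lineage genes fell, and 10 of 30 pluripotency genes rose, but no list call held with an estimated correlation. Mapt, which encodes the microtubule protein tau, was 415-fold higher (log2 8.70, SE 0.403), Fetub 185-fold, the transcriptional repressor Zbtb32 166-fold, the iron exporter Slc40a1 146-fold (log2 7.81 and 6.57 without pulsed replicate 1 and 2), Clec4a1 141-fold and the phosphatase gene Dusp14 128-fold higher (adjusted p 4.86e-10 to 9.36e-07). The largest falls were the transglutaminase chain F13a1 of monocytes, 378-fold lower (SE 1.409), Apoc2, 210-fold, the myeloid and lymphoid regulator Irf8, 206-fold, the protease inhibitor Slpi, 199-fold, Slco4a1, 194-fold, and Igsf6, 182-fold lower.

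B lineage genes fell in 16 of 27 and rose in 1 (19 changed over the list alone, median -2.39, or -2.23 with bounds, adjusted p = 6.13e-07; adjusted p = 0.0899 with an estimated correlation): the surrogate light chain gene Vpreb1 was 163-fold, Dntt 15.5-fold, Blnk 10.2-fold and the receptor chain Cd79b 6.84-fold lower. Granule genes fell in 14 of 22 (16 changed over the list alone, median -2.34, or -1.55 with bounds, adjusted p = 0.000111; adjusted p = 0.0899 with an estimated correlation), with Camp 15.6-fold and Elane 12.4-fold lower. The exception was Cebpe, a later C/EBP factor of granulocytes, at least 5.24-fold higher. Macrophage genes fell in 16 of 28 and rose in 2 (20 changed over the list alone, median -1.54, adjusted p = 0.000309; adjusted p = 0.586 with an estimated correlation), with Il1b at least 108-fold, the Fc receptor Fcgr1 at least 36.5-fold and the endotoxin coreceptor Cd14 20.7-fold lower. Stem and progenitor genes fell in 9 of 22 and rose in 4 (median -0.71, adjusted p = 0.0213; adjusted p = 0.126 with an estimated correlation), and the receptor Kit was at least 30.6-fold, Myb 45.3-fold and Flt3 28.8-fold lower.

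Pluripotency genes rose in 10 of 30 and fell in 3 (median 0.57, adjusted p = 0.00748; adjusted p = 0.281 with an estimated correlation; 0.0506 without day 1 replicate 2). Pou5f1 (Oct4, selected by the sort) was at least 86.7-fold higher, L1td1 28.6-fold, Trim71 19.1-fold and the growth factor Gdf3 15-fold higher, the last pair partly detected. The 3 that fell were Klf2, Klf4 and Esrrb. S phase genes fell in 21 of 25 (median -0.69, adjusted p = 9.19e-09). Glycolysis genes fell in 14 of 18 (17 over the list alone, median -1.09, adjusted p = 8.74e-08) and DNA methylation genes in 12 of 17 with 1 rise, Tet2 (14 changed over the list alone, median -0.74, adjusted p = 0.000461). With an estimated correlation these had an adjusted p = 0.0899 for S phase and DNA methylation and 0.099 for glycolysis. The lactate exporter Slc16a3 was 14.3-fold and the methyltransferase Dnmt3b 3.59-fold lower. Epithelial genes were not called as a list (7 rose and 5 fell of 22, adjusted p = 0.11; 0.0361 without pulsed replicate 2 and 0.0387 without day 1 replicate 1), with the cadherin Cdh1 at least 27.9-fold and the keratin Krt8 at least 44-fold higher. Class II genes fell in 6 of 12 and missed the list threshold (adjusted p = 0.0538; 0.0329 without pulsed replicate 1 and 0.0387 without day 1 replicate 1).

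Klf4 fell by 1.57 on the log2 scale (2.96-fold lower, adjusted p = 0.0155), a call lost without either pulsed array or without day 1 replicate 1. Tet2 rose a further 2.47-fold (SE 0.206, adjusted p = 0.000302). Its other probes gave log2 1.51 (adjusted p = 0.000253) and 0.26 (0.354). Kdm1a (log2 0.13), Brd4 (-0.22), Myc (0.22) and Cebpa (0.56, partly detected) did not pass, and Sox2 was below background. The Nanog probes differed: the probe used gave 0.80 (adjusted p = 0.187; 0.00527 without day 1 replicate 1), another -0.08 (0.87) and the last 2.70 (0.000154). In total 9301 genes were called, 4552 higher and 4749 lower, 5067 of them at 2-fold or more. The slide as a block gave 10651, and r across genes between the slides was 0.876.

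The step from day 1 to day 2 asked how expression moved between these days of OKSM. Most interferon genes rose and most mitotic genes fell, and 10 of 22 epithelial and 9 of 30 pluripotency genes rose. No list was called with an estimated correlation. The largest rises were Gng13, a G protein subunit, at 68-fold (log2 6.09, SE 0.446), the neuropeptide gene Agrp at 62.5-fold, the kallikrein genes Klk1b5 at 55.5-fold, Egfbp2 at 55.4-fold and Klk1b26 at 52.9-fold, and the muscle fusion gene Mymx at 54.5-fold. The cytokine gene Il6 was 13.7-fold lower (SE 0.485, adjusted p = 0.000172), Chst3 11.6-fold, Myo1f 10.5-fold, Abhd15 7.39-fold, Gng2 7.24-fold and Dixdc1 6.97-fold lower. Calls were lost for Klk1b26 without day 1 replicate 2 or day 2 replicate 2, and for Abhd15 without day 1 replicate 1 or either day 2 array. That for Dixdc1 was lost without day 2 replicate 2.

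Interferon genes rose in 20 of 23 with none lower (median 2.86, adjusted p = 2.41e-22; adjusted p = 0.087 with an estimated correlation). The antiviral genes Oas2 (23.6-fold), Rsad2 (21-fold), Mx1 (7.46-fold) and the RNA sensor Ifih1 (4.1-fold) had the smallest p. G2 and M phase genes fell in 24 of 25 (median -1.51, adjusted p = 1.02e-28; adjusted p = 0.0812 with an estimated correlation), including Ccnb2, 3.59-fold, Cdc20, 3.23-fold, and Plk1, 3.19-fold lower. S phase genes fell in 12 of 25 (13 over the list alone, median -0.37, adjusted p = 6.83e-05; adjusted p = 0.324 with an estimated correlation), such as Mcm5, 2.09-fold lower. Epithelial genes rose in 10 of 22 and fell in 1 (13 changed over the list alone, median 0.79, or 0.60 with bounds, adjusted p = 0.000277; adjusted p = 0.324 with an estimated correlation), with the keratins Krt8 35.5-fold and Krt18 4.04-fold and the desmosome gene Dsp 6.33-fold higher. Feeder and fibroblast genes, which mark the cell layer under the culture, fell in 4 of 26 (median -1.26, adjusted p = 4.25e-05; adjusted p = 0.631 with an estimated correlation). Epithelial to mesenchymal transition (EMT) genes, 3 of which are also in the feeder list, fell in 3 of 14 (4 over the list alone, median -0.75, adjusted p = 0.0163; adjusted p = 0.631 with an estimated correlation; 0.0957 without day 1 replicate 1).

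Pluripotency genes rose in 9 of 30 and fell in none (median 0.61, adjusted p = 0.0163; adjusted p = 0.532 with an estimated correlation; 0.263 without day 1 replicate 1). Gdf3 was 22.1-fold, Fbxo15, partly detected, 32.6-fold, the threonine dehydrogenase Tdh 11-fold and Lin28a 3.19-fold higher. Pou5f1 rose 5.08-fold (log2 2.35, SE 0.379, adjusted p = 0.000932). Immediate early genes rose in 7 of 17 (8 over the list alone, median 0.38, adjusted p = 0.0137; 0.158 without day 2 replicate 1). Glycolysis genes fell in 6 of 18 and rose in 1 (median -0.40, adjusted p = 0.0445; 0.343 without day 1 replicate 1 and 0.13 without day 2 replicate 2), and stem genes rose in 7 of 22 and fell in 2 (11 changed over the list alone, median 0.12, or 0.04 with bounds, adjusted p = 0.0445; 0.0624, 0.0533 and 0.0527 without day 1 replicates 1 and 2 and day 2 replicate 1). With an estimated correlation these 3 lists had an adjusted p = 0.631, 0.631 and 0.324, and with the slide as a block the glycolysis and stem calls ended at 0.0642. Kit was at least 6.07-fold and Myb 7.37-fold higher. Ribosome biogenesis genes were called as lower only without day 1 replicate 2 (adjusted p = 0.0305, against 0.21 with all arrays).

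Klf4 (log2 -1.01, adjusted p = 0.147), Myc (0.41), Kdm1a (0.30), Brd4 (0.03) and Tet2 (-0.11) did not pass, although another Tet2 probe gave -1.33 (adjusted p = 0.000525). Cebpa was detected on 1 day 1 array and on no day 2 array, which gives no size of change. For Nanog the probe used gave -1.13 (adjusted p = 0.0999; 0.00416 without day 1 replicate 1). The other probes gave 3.64 (5.97e-06) and 4.85 (4.67e-06). The direction for Nanog depends on the probe. The comparison called 4719 genes, 2669 higher and 2050 lower, 2371 of them at 2-fold or more, and 6157 with the slide as a block. Between the slides r across genes was 0.718. Counts were 3089 without day 1 replicate 2, 2826 without day 2 replicate 1, 2680 without day 2 replicate 2, 3047 from the 4 arrays alone and 7384 when both day 3 arrays were left out of the fit.

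The step from day 2 to day 3 asked what the last sampled day added. Most feeder, fibroblast and macrophage genes rose and most interferon genes fell, and again none of these list calls held with an estimated correlation. Gpnmb, a gene of macrophages and pigment cells, was 37.4-fold higher (log2 5.22, SE 0.587), the itaconate enzyme gene Acod1 29.5-fold, the chemokine genes Cxcl10 23.7-fold and Cxcl1 19.3-fold, the receptor gene Lilr4b 23.1-fold and the acute phase gene Saa3 21.3-fold higher. Without day 3 replicate 1 and without replicate 2, the log2 changes were 6.53 and 3.92 for Gpnmb, 6.05 and 3.71 for Acod1, 6.06 and 3.08 for Cxcl10, 5.46 and 3.09 for Cxcl1, 5.79 and 3.27 for Lilr4b and 5.39 and 3.44 for Saa3. Cxcl10 was also 3.83 and 5.31 without day 2 replicate 1 and 2, and Fbp1, which fell, -4.58 without day 3 replicate 1. The erythroid and megakaryocyte transcription factors Gata1 and Nfe2 were 37.6-fold and 20.1-fold lower, Drc1 37.1-fold, Pdzk1ip1 23.4-fold, the gluconeogenic enzyme gene Fbp1 15.9-fold and Mx1 13.1-fold lower (adjusted p 5.31e-07 to 0.00123). The call for Cxcl10 was lost without day 2 replicate 1 or day 3 replicate 2. Its other probe was not called (log2 1.99, adjusted p = 0.146).

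Feeder and fibroblast genes rose in 22 of 26 (24 over the list alone, median 2.56, adjusted p = 3.48e-18; adjusted p = 0.277 with an estimated correlation). The median was 1.71 on slide 1 and 3.35 on slide 2, and day 3 replicate 2 lay above replicate 1 by a median of 2.18 in 26 of 26 genes. The collagen genes Col1a1 and Col1a2 were 5.12-fold and 4.57-fold higher, the matrix gene Sparc 3.66-fold and the smooth muscle actin gene Acta2 8.6-fold higher. Col1a1 stood at 5.21 ± 0.32 in B cells, 5.37 ± 0.15 in pulsed cells, 4.38 ± 0.09 on day 1, 3.54 ± 0.51 on day 2 and 5.90 ± 1.05 on day 3, against -3.87 ± 0.04 in ES cells (SD, n = 2). Macrophage genes rose in 17 of 28 and fell in 1 (23 changed over the list alone, median 1.42, adjusted p = 9.07e-09; adjusted p = 0.349 with an estimated correlation), with Ccl4 at least 33.1-fold and Il1b at least 16.3-fold higher. Their medians were 0.61 and 2.37 on the 2 slides, and day 3 replicate 2 lay above replicate 1 by a median of 1.99. Interferon genes fell in 18 of 23 (20 changed over the list alone, median -1.97, adjusted p = 6.58e-13; adjusted p = 0.277 with an estimated correlation), with Irf7 9.7-fold and Rsad2 6.56-fold lower and 1 riser, Cxcl10. The medians were -2.85 and -1.62 on the 2 slides.

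B lineage genes fell in 8 of 27 (10 over the list alone, median -1.03, or -0.83 with bounds, adjusted p = 0.000548; adjusted p = 0.277 with an estimated correlation), such as Cd79b, 3.77-fold lower. Epithelial genes rose in 7 of 22 and fell in 1 (median 0.59, adjusted p = 0.000816; adjusted p = 0.309 with an estimated correlation), with Krt19 7.01-fold and Lsr 2.75-fold higher and Krt18 2.7-fold lower. EMT genes rose in 7 of 14 and fell in 1 (10 changed over the list alone, median 1.05, adjusted p = 0.000292). Imprinted genes rose in 7 of 22 and fell in 2 (12 changed over the list alone, median 0.73, adjusted p = 0.00488), and p53 target genes rose in 8 of 23 and fell in 2 (11 changed over the list alone, median 0.32, adjusted p = 0.00997). With an estimated correlation these had an adjusted p = 0.351, 0.351 and 0.458, without day 3 replicate 2 their calls were lost (adjusted p = 0.0767, 0.365 and 0.732), and day 3 replicate 2 lay above replicate 1 by medians of 1.6, 1.44 and 0.73. The EMT factor Twist1 was 9.58-fold, Twist2 8.33-fold, the imprinted growth regulator Grb10 4.85-fold and the stress cytokine Gdf15 11.8-fold higher.

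Pluripotency genes rose in 6 of 30 and fell in 2 (median 0.06, adjusted p = 0.043; adjusted p = 0.448 with an estimated correlation). That call was lost without day 2 replicate 2 (0.136) or day 3 replicate 1 (0.233). Tbx3 was 6.7-fold, Zic3, partly detected, 6.86-fold and Nr0b1 at least 2.07-fold higher, and the Nodal inhibitor Lefty2 3.8-fold lower. Chromatin regulators fell in 7 of 27 and rose in 1 (10 changed over the list alone, median -0.34, adjusted p = 0.00488; adjusted p = 0.458 with an estimated correlation), with Suz12 of the Polycomb complex 2.75-fold lower. The called lists with fewer changed members were glycolysis (2 rose and 1 fell of 18, 2 changed over the list alone, adjusted p = 0.00434), oxidative phosphorylation (3 fell of 24, 1 over the list alone, 0.00488), T and NK cell genes (5 fell of 16, 6 over the list alone, 0.00997) and megakaryocyte and erythroid genes (2 rose of 14, 0.0116). In that order these had an adjusted p = 0.351, 0.618, 0.309 and 0.277 with an estimated correlation. The oxidative phosphorylation and megakaryocyte calls were lost without day 3 replicate 2 (0.369 and 0.125), and the T cell call without day 2 replicate 2 (0.0693) or day 3 replicate 1 (0.104). Other lists were called only without 1 array: immediate early genes (0.00446 without day 2 replicate 1; 0.0402 without day 3 replicate 1), granule genes (0.0315 without day 3 replicate 1, median -0.16, mean 0.33) and G2 and M phase genes (0.00104 without day 3 replicate 2).

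Klf4 rose 3.34-fold (log2 1.74, SE 0.449, adjusted p = 0.0179; up to 0.103 without either day 2 array), and Cebpa was at least 5.73-fold higher (adjusted p = 0.00496; 0.0542 without day 2 replicate 1). The day 3 arrays differed: without replicate 1 and without replicate 2 Klf4 was 2.78 and 0.70, and Cebpa, unbounded, 3.92 and 1.84. Kdm1a fell by 0.55 (adjusted p = 0.0196) and Tet2 by 0.65 (0.0446). Both calls were lost without either day 2 array or without day 3 replicate 2. Pou5f1 (0.13, 0.875) did not pass, nor did Myc (-0.74, 0.102) or Brd4 (-0.50, 0.108), which were called without day 3 replicate 1 (7.8e-05 and 0.0102). The Nanog probe used gave 0.24 (0.78), and the others -1.21 (0.016) and -1.90 (0.00588). The comparison called 5038 genes, 2159 higher and 2879 lower, 2631 of them at 2-fold or more, and 6812 with the slide as a block. The differences on the slides correlated at r = 0.654 across genes, and those of called genes had a median size of 0.766 on slide 1 and 1.273 on slide 2. The count was 2246 without day 2 replicate 1, 2548 without day 2 replicate 2, 10300 without day 3 replicate 1 and 3109 without day 3 replicate 2. It was 21 when only the 4 arrays were fitted with limma, where 3724 genes had an unadjusted p under 0.05.

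By stage, 16 of the 30 pluripotency genes were well above background on both arrays in B cells, 14 in pulsed cells, 17 on day 1, 19 on day 2 and 20 on day 3, and all 30 in iPS and ES cells. Nanog counts among them in B cells and pulsed cells only by the probe that is low in ES cells. Pou5f1, selected by the sort, and Fgf4 were first detected on day 1, Dppa5a and Fbxo15 on day 2 and Nr0b1 on day 3, and 9 were detected at none of these stages. Sox2 is among the 9, by a probe not shown to detect the induced transcript. All 27 B lineage genes were detected in B cells and in pulsed cells, 21 on day 1, 23 on day 2 and 21 on day 3, and 15 and 17 in iPS and ES cells.

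**Figure D2:**
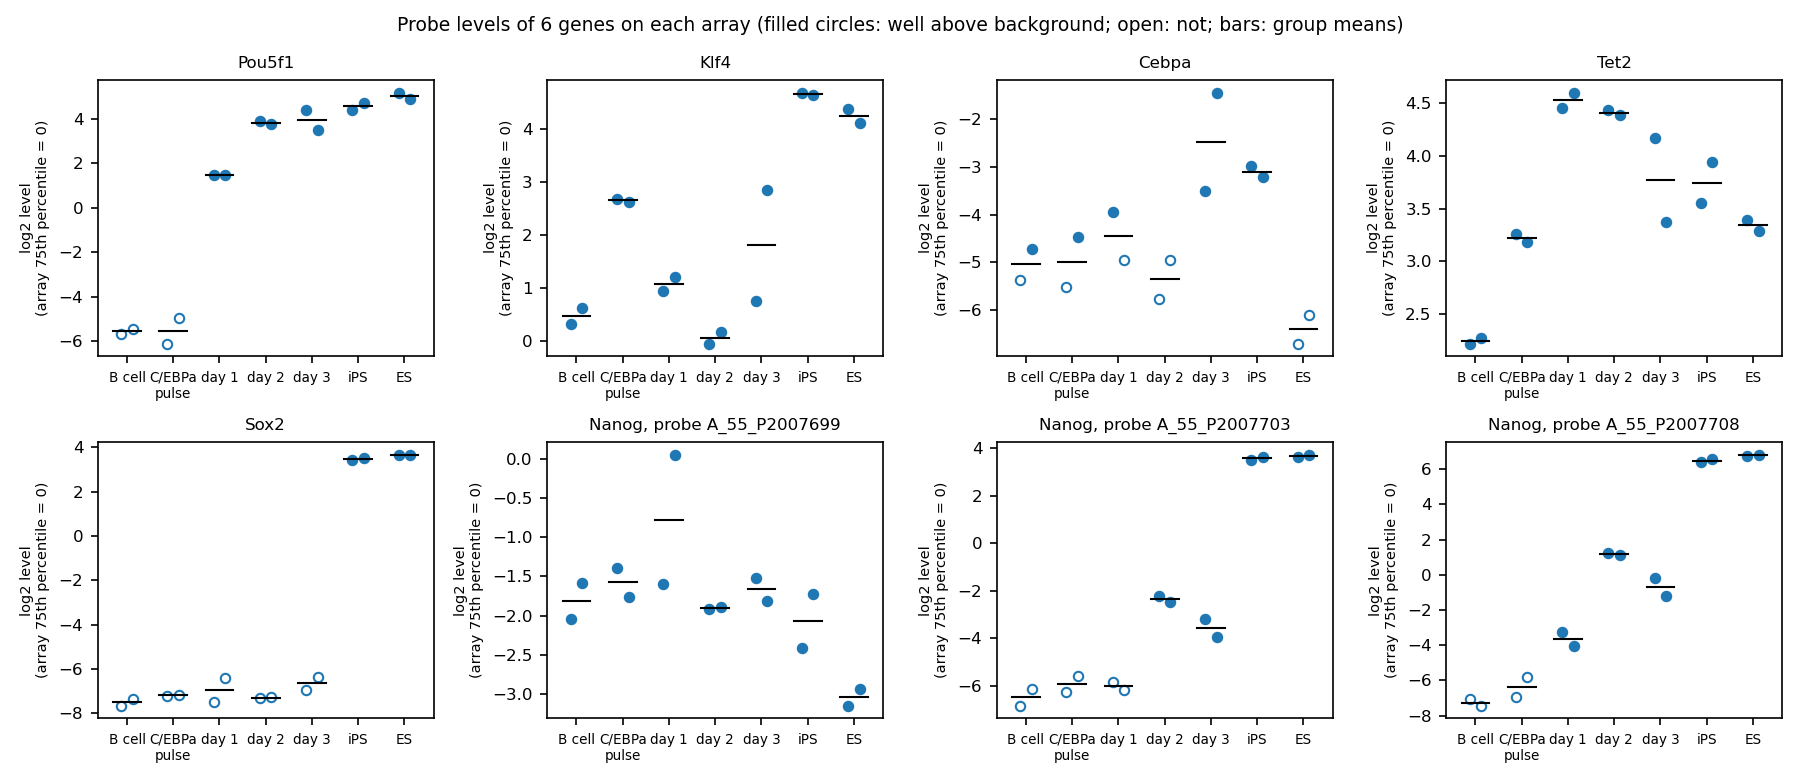
Log2 level of single genes relative to each array's 75th percentile (vertical axis) by group (horizontal axis). Filled circles are well above background, open circles are not, bars are group means, and Nanog is drawn for 3 probes. Klf4 goes from 0.47 in B cells to 2.65 in pulsed cells and 0.07 on day 2, and Pou5f1 from 1.48 on day 1 to 3.83 on day 2.

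Day 3 cells were set against ES cells to ask how far they stood from pluripotent cells. Most pluripotency and cell cycle genes were lower on day 3, and most fibroblast, macrophage and interferon genes were higher, with no list called at an estimated correlation. Col1a2 was 3830-fold (log2 11.90, SE 0.365), the imprinted transcript H19 2580-fold, Ugt1a6b 1130-fold, Col1a1 874-fold, Pi16 710-fold and Mgst2 697-fold higher. Dppa5a, a gene of naive pluripotent cells, was 4520-fold lower (SE 0.579), the nuclear receptor genes Esrrb 511-fold and Nr0b1 457-fold, Bex1 442-fold, Zfp979 416-fold and Gpat2 360-fold lower (adjusted p 2.24e-10 to 4.53e-09). Without day 3 replicate 1 and without replicate 2, log2 values were 12.64 and 11.16 for Col1a2, 12.30 and 10.37 for H19, 10.52 and 9.03 for Col1a1, -9.68 and -8.31 for Esrrb, -7.81 and -9.77 for Bex1 and -8.11 and -9.30 for Zfp979.

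Pluripotency genes were lower in 29 of 30 (median -6.28, or -5.99 with bounds, adjusted p = 2.11e-10; adjusted p = 0.0673 with an estimated correlation): Utf1 was 187-fold, Sox2 at least 428-fold, Tcl1 at least 1720-fold and Zfp42 at least 3900-fold lower. The exception was Nanog by the probe used, at 1.38 (adjusted p = 0.0157; 0.0768 at most without day 3 replicate 1 or ES replicate 1), while its other probes gave -7.26 (9.25e-10) and -7.51 (5.67e-09). G2 and M phase genes were lower in 25 of 25 (median -2.57, adjusted p = 9.88e-12) and S phase genes in 23 of 25 (median -2.20, adjusted p = 2.16e-10), with Bub1 15.7-fold and Mcm3 6.29-fold lower. These had an adjusted p = 0.173 and 0.0673 with an estimated correlation. Feeder and fibroblast genes were higher in 25 of 26 (median 7.01, or 6.09 with bounds, adjusted p = 1.7e-11), macrophage genes in 25 of 28 (median 4.57, or 3.25 with bounds, adjusted p = 3.52e-10) and interferon genes in 17 of 23 with 1 lower (median 5.33, or 4.40 with bounds, adjusted p = 2.19e-07), each with an adjusted p = 0.241 with an estimated correlation. ES cells were grown without feeder cells, on gelatin in 2i medium with LIF.

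Other lists followed. Immediate early genes were higher in 11 of 17 (12 over the list alone, median 2.35, adjusted p = 9.4e-05; adjusted p = 0.241 with an estimated correlation), with Fos 180-fold higher. EMT genes were higher in 9 of 14 (median 2.35, adjusted p = 0.000826; adjusted p = 0.281 with an estimated correlation), class II genes in 8 of 12 (median 1.84, or 1.71 with bounds) and stem genes in 13 of 22 with 3 lower (median 1.49), the last pair with an adjusted p = 0.00177, and 0.0673 with an estimated correlation. B lineage genes were higher in 12 of 27 and lower in 1 (12 changed over the list alone, median 0.74, adjusted p = 0.0189; adjusted p = 0.281 with an estimated correlation), with Il7r at least 121-fold higher. Ribosome biogenesis genes were lower in 20 of 24 (21 over the list alone, median -0.99, adjusted p = 0.000146), glycolysis genes in 14 of 18 with 1 higher (16 changed over the list alone, median -1.21, adjusted p = 0.00315) and oxidative phosphorylation genes in 14 of 24 (median -0.62, adjusted p = 0.00316). Taken in order, they had an adjusted p = 0.33, 0.281 and 0.48 with an estimated correlation. Chromatin regulators were lower in 14 of 27 and higher in 3 (median -0.88, adjusted p = 0.03; 0.0878 without day 3 replicate 2), primed epiblast genes lower in 12 of 16 and higher in 3 (median -2.36, or -1.69 with bounds, adjusted p = 0.0167; 0.0671 without day 3 replicate 1) and early embryo genes lower in 8 of 12 (median -2.99, or -1.40 with bounds, adjusted p = 0.0243; 0.0528 without day 3 replicate 1). These lists had, in order, an adjusted p = 0.48, 0.241 and 0.328 with an estimated correlation. Granule genes (0.0214) and p53 target genes (0.00203) were called as higher only without day 3 replicate 1.

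Klf4 was 5.4-fold lower (SE 0.449, adjusted p = 0.000414), Kdm1a 3.39-fold lower (3.42e-07), Brd4 1.84-fold lower (0.00219), Myc 9.12-fold higher (9.91e-07) and Cebpa at least 6.26-fold higher (6.57e-05) on day 3 than in ES cells. Without day 3 replicate 1 and without replicate 2 the log2 values were -1.39 and -3.48 for Klf4, 2.56 and 3.82 for Myc and, unbounded, 4.97 and 2.89 for Cebpa. Pou5f1 was 2.13-fold lower (0.0237; 0.215 without day 3 replicate 2 and 0.114 without ES replicate 1). Tet2 gave 0.42 (0.0916; 0.000427 without day 3 replicate 2), and another of its probes -0.79 (0.00354). The comparison called 16173 genes, 7098 higher and 9075 lower, 11210 of them at 2-fold or more. Slides and groups cannot be separated here.

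The iPS cells were set against ES cells to ask where established pluripotent lines differed. Of the pluripotency genes 6 of 30 differed, and most fibroblast, interferon, macrophage and immediate early genes were higher in iPS cells. None of the list calls held with an estimated correlation. Col1a2 was 1250-fold (log2 10.29, SE 0.365) and Col1a1 285-fold higher, the interferon-induced genes Irgm1 687-fold, Isg15 297-fold and Lgals3bp 201-fold higher, and Hprt, of purine salvage, which the E14TG2 line lacks, 250-fold higher. Lower were Dpys, of pyrimidine breakdown, 57-fold (SE 0.44), Olfr224 50.7-fold, Rhox2h 32-fold, Defa1 28.7-fold, Xlr4a 27.6-fold and Fxyd2 27.1-fold (adjusted p 9.91e-11 to 0.0021). Without iPS replicate 1 and without replicate 2 Rhox2h was -6.30 and -3.70 and Xlr4a -7.03 and -2.54.

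Of 30 pluripotency genes 4 were higher, 2 lower and 24 did not pass (median 0.06, adjusted p = 0.345): the Nodal coreceptor Tdgf1 was 8.45-fold and Sall4 1.85-fold higher, and Zfp42 11.4-fold and Tfcp2l1 3.44-fold lower. Sox2 (-0.20), Pou5f1 (-0.47), Klf4 (0.42), Nanog (0.98), Kdm1a (-0.29), Brd4 (-0.15) and Tet2 (0.41) did not pass. Myc was 3.7-fold higher (adjusted p = 0.000354) and Cebpa at least 4.06-fold higher (0.000831). Feeder genes were higher in 24 of 26 (25 over the list alone, median 5.98, or 5.11 with bounds, adjusted p = 8.15e-21; adjusted p = 0.118 with an estimated correlation). Interferon genes were higher in 22 of 23 (median 7.69, or 6.26 with bounds, adjusted p = 5.12e-26), immediate early genes in 13 of 17 (14 over the list alone, median 2.15, adjusted p = 7.65e-11) and macrophage genes in 20 of 28 with 2 lower (23 changed over the list alone, median 2.55, or 1.96 with bounds, adjusted p = 2.17e-10). In the same order they had an adjusted p = 0.102, 0.102 and 0.204 with an estimated correlation.

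Early embryo genes were higher in 9 of 12 (10 over the list alone, median 2.42, or 1.98 with bounds, adjusted p = 2.96e-05; adjusted p = 0.118 with an estimated correlation), among them Zscan4c 7.93-fold and Zscan4e 5.91-fold, markers of a cell state resembling the early cleavage embryo. Primed epiblast and mesendoderm genes were higher in 9 of 16 and lower in 1 (median 1.60, adjusted p = 6.39e-05; adjusted p = 0.108 with an estimated correlation), with the epiblast factor Pou3f1 8.28-fold and the endoderm genes Dab2 at least 35.9-fold and Gata6 at least 35.7-fold higher. Higher lists were also EMT (6 of 14, adjusted p = 3.75e-05), granule (6 of 22 with 1 lower, 0.00411), mast cell (4 of 18, 0.00621), stem (8 of 22 with 3 lower, 0.0208) and B lineage genes (6 of 27 with 2 lower, 0.048; 0.0703 without ES replicate 1 and 0.53 without iPS replicate 1). They had, in this order, an adjusted p = 0.204, 0.118, 0.108, 0.118 and 0.363 with an estimated correlation. Lower lists were S phase (17 of 25 with 1 higher, 21 changed over the list alone, adjusted p = 0.000336), oxidative phosphorylation (12 of 24, 14 over the list alone, 0.00349) and G2 and M phase genes (9 of 25, 0.0208; 0.119 without iPS replicate 1). In that order these had an adjusted p = 0.204, 0.653 and 0.653 with an estimated correlation. Class II genes were called only without ES replicate 2 (0.0373) and p53 target genes only without iPS replicate 2 (0.0245). The comparison called 8987 genes, 3664 higher and 5323 lower, 4650 of them at 2-fold or more. Each group had its own slide, and the culture of the iPS cells is not in the sample labels.

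Pulsed cells were set against GMPs named total by source to ask how near they came to natural myeloid progenitors. Most B lineage and fibroblast genes were higher in pulsed cells, and most granule, mast cell, erythroid and class II genes were lower. All of these list calls but that for fibroblast genes held with an estimated correlation. Sparc was 1560-fold (log2 10.61, SE 0.222), Col1a2 557-fold and Apoc1 522-fold higher, and the surrogate light chain genes Vpreb3 1230-fold, Igll1 428-fold and Vpreb1 342-fold higher. Ms4a3, a marker of granulocyte-monocyte progenitors, was 1530-fold lower (SE 0.378), the chitinase-like gene Chil3 446-fold, the granule peroxidase Mpo 363-fold, Acod1 287-fold and the neutrophil calcium-binding genes S100a9 280-fold and S100a8 214-fold lower (adjusted p 1.84e-09 to 3.08e-05). Without pulsed replicate 1 and without replicate 2 S100a9 was -6.96 and -9.29 and S100a8 -6.84 and -8.65.

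B lineage genes were higher in 25 of 27 (median 5.67, or 4.25 with bounds, adjusted p = 2.48e-16; adjusted p = 0.00343 with an estimated correlation), such as the receptor chain Cd79a at 245-fold and the transcription factor Lef1 at 221-fold. Feeder genes were higher in 23 of 26 (24 over the list alone, median 7.07, or 5.90 with bounds, adjusted p = 3.05e-15; adjusted p = 0.228 with an estimated correlation), EMT genes in 11 of 14 with 1 lower (adjusted p = 9.84e-05) and imprinted genes in 12 of 22 with 2 lower (15 changed over the list alone, 0.00241), these with an adjusted p = 0.319 and 0.331 with an estimated correlation. Granule genes were lower in 14 of 22 and higher in 3 (18 changed over the list alone, median -3.78, adjusted p = 3.09e-05; adjusted p = 0.0286 with an estimated correlation), with Cebpe at least 954-fold lower. Megakaryocyte and erythroid genes were lower in 12 of 14 (median -3.23, or -2.45 with bounds, adjusted p = 1.48e-07), class II genes in 10 of 12 with 1 higher (median -2.87, adjusted p = 0.000318) and mast cell genes in 13 of 18 with 3 higher (17 changed over the list alone, median -4.82, or -3.56 with bounds, adjusted p = 0.000392). Taken in order, they had an adjusted p = 0.00343, 0.0265 and 0.0265 with an estimated correlation. H2-Aa was 60.4-fold and the mast cell protease Cpa3 at least 327-fold lower. Lower lists were also stem (13 of 22 with 4 higher, adjusted p = 0.00289), S phase (13 of 25, 0.00289), G2 and M phase (15 of 25 with 1 higher, 0.000849), macrophage (14 of 28 with 2 higher, 0.00592) and epithelial genes (8 of 22 with 2 higher, 0.00593). Over the list alone 18 stem, 17 G2 and M phase and 17 macrophage genes changed. These lists had, in order, an adjusted p = 0.055, 0.363, 0.517, 0.654 and 0.361 with an estimated correlation. Immediate early genes were called as lower only without pulsed replicate 1 (0.0494) or total GMP replicate 1 (0.0457), and oxidative phosphorylation only without pulsed replicate 2 (0.0321) or total GMP replicate 2 (0.0221).

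Cebpa, partly detected in pulsed cells by a probe not shown to detect the induced transcript, was 128-fold lower than in GMPs (adjusted p = 1.25e-06), Klf4 did not pass (-0.23, 0.705) and Brd4 was 1.97-fold higher (0.00188). Nanog was 2.65-fold higher by the probe that is low in ES cells (0.02; 0.134 at most without pulsed replicate 1 or total GMP replicate 2), and its other probes were below background in both groups. Myc (-0.36), Kdm1a (-0.13) and Tet2 (-0.06) did not pass. Pou5f1 and Sox2 were below background in both groups. The comparison called 11823 genes, 5837 higher and 5986 lower, 6614 of them at 2-fold or more. The cells came from different cultures, arrays and slides, and the titles call the GMPs used here slow.

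The GMP comparisons asked how progenitors named fast dividing differ from those named slow and from the total. Most mast cell, megakaryocyte and mitotic genes and some stem and granule genes were lower in the group named fast than in the group named slow, and most S phase genes were higher. Against the group named slow, the basophil protease Prss34 was 89.2-fold lower (log2 -6.48, SE 0.501, adjusted p = 8.82e-06), the serotonin enzyme gene Tph1 and the eosinophil protein gene Prg2 each 24.4-fold, the IgE receptor chain Fcer1a 22.1-fold, the cytotoxic protease Gzmb 21.9-fold and Cavin2 20.7-fold lower. The largest rises were smaller, and of them Ms4a4b, 3.52-fold higher (adjusted p = 0.00191), held without any single array. Foxj1 (3.9-fold, adjusted p up to 0.18; log2 2.64 and 1.29 without fast replicate 1 and 2) lost its call without fast replicate 2 or either slow array, and Tctex1d1 (3.86-fold, up to 0.172), Myadml2 (3.85-fold, 0.162), Fcgrt (3.14-fold, 0.0953) and Ly86 (2.83-fold, 0.109) lost theirs without any 1 of the 4 arrays.

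Mast cell, basophil and eosinophil genes were lower in 14 of 18 (15 over the list alone, median -3.69, or -3.53 with bounds, adjusted p = 9.15e-21; adjusted p = 8.35e-05 with an estimated correlation). Megakaryocyte and erythroid genes were lower in 10 of 14 (11 over the list alone, median -2.01, or -1.91 with bounds, adjusted p = 6.64e-13; adjusted p = 0.000303 with an estimated correlation): Pf4 of platelets was 15.9-fold, Ppbp at least 27.4-fold and the erythropoietin receptor Epor 6.99-fold lower. Stem and progenitor genes were lower in 7 of 22 (9 over the list alone, median -0.60, adjusted p = 1.33e-08; adjusted p = 0.00211 with an estimated correlation), with Meis1 2.96-fold lower. Granule genes were lower in 9 of 22 (10 over the list alone, median -1.45, adjusted p = 3.21e-07; adjusted p = 0.0134 with an estimated correlation), with Camp 18.1-fold lower. G2 and M phase genes were lower in 15 of 25 (19 over the list alone, median -0.73, adjusted p = 2.92e-19), with Ube2c 3.69-fold and Ccnb1 3.22-fold lower. S phase genes were higher in 16 of 25 (18 over the list alone, median 0.58, adjusted p = 6.03e-11), with Ccne1 2.8-fold and Cdc6 2.03-fold higher. Both lists had an adjusted p = 0.0457 with an estimated correlation.

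Other lists lower in the group named fast were p53 targets (8 of 23, adjusted p = 1.76e-09), interferon (4 of 23, 0.000117), B lineage (5 of 27 with 1 higher, 0.000485), imprinted (8 of 22, 0.000654), T and NK cell (4 of 16, 0.000654) and feeder genes (5 of 26, 0.0298; 0.0557 without fast replicate 2 and 0.0713 without slow replicate 1). In the same order they had an adjusted p = 0.089, 0.444, 0.111, 0.241, 0.089 and 0.773 with an estimated correlation. Oxidative phosphorylation (1 higher of 24, 14 over the list alone, adjusted p = 1.38e-05), ribosome biogenesis (4 of 24, 0.000251) and glycolysis genes (4 of 18 with 1 lower, 0.0461) were higher. Over the list alone 11 p53 targets, 5 interferon, 7 B lineage, 7 T and NK cell, 6 ribosome and 9 glycolysis genes changed. They had, in this order, an adjusted p = 0.496, 0.496 and 0.543 with an estimated correlation. Antibody genes, looked at after their values were seen, were lower too: 78 of 187 genes in the immunoglobulin loci with 2 higher, and the joining chain gene Jchain at least 34.4-fold. The glycolysis call was lost without fast replicate 1 (0.0843), fast replicate 2 (0.063), slow replicate 1 (0.0691) or slow replicate 2 (0.0586). For EMT genes (median 0.32, test downward), class II genes (median 0.14, test downward) and epithelial genes (median 0.23, mean -0.02), none called, the median and the test or mean differed in sign. The comparison called 2434 genes, 908 higher and 1526 lower, 1246 of them at 2-fold or more. It called 1299 without fast replicate 1, 1409 without fast replicate 2, 1028 without slow replicate 1, 1047 without slow replicate 2, 533 with the groups taken from the titles and 206 from the value table. With the titles, which exchange slow and total, 68 were higher and 465 lower, and of 450 genes called under both groupings 1 turned. In the value table, whose GMP columns match other arrays than their own, 166 of 168 shared calls turned, and in the other alternatives none did.

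Between the groups named fast and total, 533 genes were called, 68 higher and 465 lower in the fast group, 347 of them at 2-fold or more. The count was 300 without total replicate 2. The split moved to 209 higher and 291 lower without fast replicate 1 (41.8% higher) and 203 and 270 without fast replicate 2 (42.9%), from 12.8%. It was 0 when only the 4 arrays were fitted with limma, where 5401 had an unadjusted p under 0.05. The heme oxygenase gene Hmox1 was 15.1-fold (SE 0.327, adjusted p = 0.000133), Prss34 14.4-fold, the granule genes Ngp 9.52-fold and Camp 7.13-fold, Tph1 7.34-fold and Fcer1a 7.29-fold lower. Another Hmox1 probe gave log2 -1.9. The call for Tph1 was lost without total replicate 2. Gzmm was 2.9-fold higher (0.000948), and the other rises, D4Ertd617e (2.46-fold), Saysd1 (2.34-fold), Ankrd24 (1.93-fold), Arl6ip5 (1.86-fold) and Ppp1r18 (1.81-fold), did not hold. D4Ertd617e, Ankrd24 and Ppp1r18 lost their calls without any 1 of the 4 arrays. Saysd1 lost its call without total replicate 2 or fast replicate 1, and Arl6ip5 without total replicate 2 or either fast array. Mast cell genes were lower in 10 of 18 (14 over the list alone, median -2.22, adjusted p = 7.28e-18), megakaryocyte genes in 6 of 14 (9 over the list alone, median -1.18, or -0.70 with bounds, adjusted p = 1.38e-10), G2 and M phase genes in 10 of 25 (19 over the list alone, median -0.68, adjusted p = 1.49e-23), granule genes in 5 of 22 (6 over the list alone, median -0.69, adjusted p = 4.83e-07) and stem genes in 4 of 22 (5 over the list alone, median -0.27, adjusted p = 4.26e-05). In that order these had an adjusted p = 0.000178, 0.000729, 0.0298, 0.0137 and 0.0137 with an estimated correlation. S phase genes were higher in 4 of 25 (8 over the list alone, median 0.29, adjusted p = 9.9e-07; adjusted p = 0.146 with an estimated correlation). The other called lists were p53 targets (3 lower of 23, adjusted p = 4.83e-07), B lineage (4 lower of 27, 0.012), immediate early (1 lower of 17, 0.0104), T and NK cell (2 lower of 16, 0.0499) and, with none changed, interferon (0.0251), ribosome biogenesis (0.0104) and oxidative phosphorylation genes (0.0101). With an estimated correlation their adjusted p ran from 0.194 to 0.637. Over the list alone 8 p53 targets, 5 B lineage, 2 immediate early and 3 interferon genes changed. T and NK cell genes had a median of 0.05 and a mean of -0.26. Without total replicate 2 the B lineage, interferon, oxidative phosphorylation and ribosome calls were lost. Without fast replicate 2 those for interferon, ribosome and T and NK cell genes were lost. Without total replicate 1 the T and NK cell call was lost (0.125), and feeder (0.0382) and glycolysis genes (0.0186) were called.

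Between the groups named slow and total, 269 genes were called, 222 higher and 47 lower in the slow group (82.5% higher), 221 of them at 2-fold or more. The split was 137 higher and 195 lower without total replicate 1 (41.3%) and 127 and 122 without total replicate 2 (51%). The platelet genes Ppbp (8.3-fold, SE 0.374), Pf4 (5.15-fold) and Gp1ba (4.9-fold), Cavin2 (4.68-fold) and the mast cell proteases Prss34 (6.18-fold) and Cma1 (4.75-fold) were higher, and Hmox1 10.3-fold (SE 0.327, adjusted p = 0.000548), Ms4a4b 2.95-fold, Sertad3 2.85-fold, Alg8 2.61-fold, and Traip and Ube1y1 each 2.56-fold lower. Calls were lost without any 1 of the 4 arrays for Prss34 (up to 0.126), Gp1ba (0.106), Cavin2 (0.208) and Traip (0.161). They were also lost without total replicate 2 or either slow array for Cma1 (0.0644) and Alg8 (0.0801), without total replicate 1 or either slow array for Ms4a4b (0.132), and without slow replicate 2 for Ube1y1 (0.0894). In the immunoglobulin loci 53 of 187 genes were higher in the slow group and 1 lower, Jchain was at least 52.4-fold and Iglv1 at least 18-fold higher, and Jchain was above background on both slow arrays alone among the GMP arrays. Mast cell genes were higher in 2 of 18 (11 over the list alone, median 1.37, adjusted p = 3.74e-15), megakaryocyte genes in 3 of 14 (6 over the list alone, median 0.87, adjusted p = 1.11e-10) and stem genes in 2 of 22 (4 over the list alone, median 0.38, adjusted p = 6.48e-07). Taken in order, they had an adjusted p = 0.000344, 0.000653 and 0.00473 with an estimated correlation. S phase genes were lower in 1 of 25 (5 over the list alone, median -0.26, adjusted p = 1.66e-08; adjusted p = 0.112 with an estimated correlation). Other lists called here were imprinted (2 higher of 22, adjusted p = 0.000249), interferon (2 higher of 23, 0.000352), granule (1 higher of 22, 0.00201) and, with none changed, p53 target (0.000619), oxidative phosphorylation (0.000318), T and NK cell (0.00268), ribosome (0.0107), B lineage (0.0136) and G2 and M phase genes (0.0136). With an estimated correlation their adjusted p ran from 0.134 to 0.719. Without total replicate 1 the B lineage (0.186), G2 and M phase (0.163) and ribosome calls (0.213) were lost, and without slow replicate 1 the G2 and M phase call (0.0643). Feeder genes were called without total replicate 2 (0.0192) or slow replicate 2 (0.0419) and glycolysis genes without total replicate 2 (0.0273). Over the list alone 5 interferon and 3 T and NK cell genes changed. The titles exchange these groups, so by the titles each sign here turns.

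The share of called genes that were higher moved by more than 10 points in the value table, to 73.7% from 56.6% for day 2 against day 1, 54% from 40.8% for iPS against ES cells, 63.7% from 49.4% for pulsed cells against GMPs, 89.3% from 37.3% for fast against slow, 93% from 12.8% for fast against total and 93.7% from 82.5% for slow against total GMPs. With the GMP columns of the value table moved to the arrays they match, it was 58.3% for pulsed cells against GMPs, 7% for fast against slow, 6.3% for fast against total and 89.3% for slow against total. For fast against slow it moved to 52.6% with the array median as the scale, 59% from the 4 arrays alone, 54.3% without both day 3 arrays, 15.5% (159 higher and 869 lower) without slow replicate 1 and 16% (168 and 879) without slow replicate 2. Without both day 3 arrays it moved to 25.8% for fast against total and 68.8% for slow against total, and from the 4 arrays alone to 28.6% for day 3 against day 2. The median change over all genes was -0.127 for day 3 against day 2, -0.12 for day 3 against ES cells, -0.144 for iPS against ES cells and 0.158 for fast against slow GMPs, and within 0.1 of 0 in the other 6 comparisons. Leaving out the filter on dim probes, the array median, quantile and normexp scales and the value table each moved this median by more than 0.1 in at least 1 comparison, by at most 0.19 (value table, pulsed cells against GMPs). With the GMP columns of that table moved, the median for fast against slow GMPs went further, from 0.158 to -0.079.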

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

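The crossed pairing of the pulsed arrays, the value table with its GMP columns moved to the arrays they match, the fits without both day 3 arrays, the slide as a block in the list tests and the list tests with 1 array left out were chosen only after the results were seen. Of 162 counts of called genes under the alternatives, 131 stayed within 1.5-fold, 21 fell further and 10 rose further. Of 2100 list results 1829 kept their side of the threshold and, but for 91 uncalled ones, their direction, 195 lost a call, 44 gained a call and 32 reversed. Of 2951 named gene results 2715 kept theirs, 29 of them uncalled with a sign change, 174 were weaker, 28 stronger and 34 reversed. All 28 detection counts were within 1.5-fold. The cause was tested only for the reversals of GMP comparisons in the value table: with its GMP columns moved to the arrays they match, the genes called in the opposite direction went from 166 for fast against slow, 415 for fast against total and 16 for slow against total to 0 in each, and the reversed named genes from 30 to 1. Leaving out arrays also leaves fewer samples. A gene below background is not shown to be silent.

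The replicate numbers were not treated as pairing the samples. Deviations from group means of equally numbered arrays correlated at -0.32 to -0.11 for the 4 pairs with pulsed cells and 0.08 to 0.33 for the other 6 pairs of the B cell series. With the replicate block the count for slow against total GMPs was 167 (from 269), and the other 9 counts stayed within 1.5-fold. With the pulsed numbers crossed, 5446 were called for pulsed against B cells and 10102 for day 1 against pulsed cells.

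Counts of called genes moved by more than 1.5-fold as follows. With 1 array left out they ran from 2949 to 3317 for pulsed against B cells, 2680 to 3871 for day 2 against day 1, 2246 to 10300 for day 3 against day 2, 1028 to 1409 for fast against slow and 300 to 500 for fast against total GMPs. Fitted from the 4 arrays alone they were 3047 for day 2 against day 1, 21 for day 3 against day 2, 6611 for fast against slow and 0 for fast against total. With both day 3 arrays left out they were 7384 for day 2 against day 1, 5468 for fast against slow, 1616 for fast against total and 776 for slow against total. The value table gave 206 for fast against slow, 1852 for fast against total and 489 for slow against total. The titles gave 533 for fast against slow, quantile scaling 808 and no filter on dim probes 355 for fast against total, and normexp with quantile scaling 424 for slow against total.

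Gene list calls depended most on the correlation within lists. With an estimated correlation the lists called numbered 2 for pulsed against B cells, 0 in each of the next 5 comparisons, from day 1 against pulsed cells to iPS against ES cells, 5 for pulsed cells against GMPs, 6 for fast against slow, 5 for fast against total and 3 for slow against total GMPs, against 12, 8, 10, 14, 17, 14, 13, 15, 13 and 13 with the preset one. Quantile scaling left 9 lists for iPS against ES cells. With 1 array left out no list reversed.

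Reversed list medians came from the value table but for 1, glycolysis in fast against slow GMPs at 0.02 with quantile scaling, where the test turned downward. In the value table the G2 and M phase list was 0.46 for pulsed cells against GMPs. For fast against slow GMPs it gave B lineage 0.28, feeder 0.16, G2 and M phase 0.14, glycolysis -0.09, granule 0.47, imprinted 0.63, interferon 0.4, mast cell 1.47, megakaryocyte 0.9, oxidative phosphorylation -0.1, p53 0.29, ribosome -0.04, S phase -0.16, stem 0.44 and T and NK cell 0.38. For fast against total it gave B lineage 0.68, G2 and M phase 0.84, granule 1.71, immediate early 0.28, imprinted 1.09, interferon 0.67, mast cell 3.73, megakaryocyte 2.04, oxidative phosphorylation -0.14, p53 0.71, ribosome -0.13, S phase -0.32, stem 0.82 and T and NK cell 0.82, and for slow against total immediate early 0.39. Lists were not tested with the GMP columns moved.

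Named genes that reversed in the value table were, for fast against slow GMPs, Foxj1 -0.35, Tctex1d1 -1.20, Myadml2 -0.65, Ms4a4b -1.36, Fcgrt -0.69, Ly86 -0.67, Prss34 2.72, Tph1 1.81, Prg2 2.13, Fcer1a 1.68, Gzmb 1.85 and Cavin2 2.28. For fast against total they were Gzmm -0.48, D4Ertd617e -0.86, Saysd1 -0.39, Ankrd24 -0.76, Arl6ip5 -0.54, Ppp1r18 -0.08, Hmox1 0.76, Prss34 6.30, Ngp 4.46, Tph1 4.57, Fcer1a 4.36 and Camp 4.37, and for slow against total Hmox1 3.94, Sertad3 2.33, Alg8 1.58, Traip 2 and Ube1y1 1.47. Sox2, below background in both groups, was 1.80 for pulsed cells against GMPs in the value table and 1.79 with its GMP columns moved, and no other named gene stayed reversed with these columns moved. Fast against slow then had 130 genes higher and 1722 lower, with none opposite. With the mean of a gene's probes Nanog was 2.45 for day 2 against day 1, -0.96 for day 3 against day 2 and -4.47 for day 3 against ES cells.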

Other observations

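The tests of the GMP labels, of the interferon genes and of day 3 replicate 2 were chosen only after the results were seen. The test of feeder RNA on day 3 was written before.

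The largest rise on day 1 was Mapt, the gene of the microtubule protein tau, 415-fold, and among the largest on day 2 were Agrp, a hypothalamic neuropeptide, 62.5-fold, and the kallikrein genes Klk1b5, 55.5-fold, and Egfbp2, 55.4-fold, none of them a gene of B cells or of pluripotent cells by background knowledge. Gata1, the regulator of erythroid and megakaryocyte cells, stood at 1.29 ± 0.03 on day 2 and at -3.95 ± 0.50 on day 3, and Nfe2 at 1.78 ± 0.10 and -2.55 ± 0.50 (SD, n = 2).

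Feeder and fibroblast genes were higher on day 3 than on day 2. Day 3 replicate 2 alone is excluded as the whole cause, since on the other slide the list was also higher, by a median of 1.71 (quartiles 1.49 and 2.04, 26 genes). RNA of feeder cells left after pre-plating is consistent with these values, since it would move all its genes alike and the changes of the 26 genes had an interquartile range of 0.46 (2.27 to 2.73). No biological explanation was tested, and a change in the sorted cells themselves stays open.

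Interferon genes were higher on day 2 than on day 1. More feeder cell RNA is excluded as the cause, since the feeder and fibroblast list moved the other way, with a median of -1.26 (quartiles -1.35 and -0.92). A single slide is excluded too, since the smaller of the slide medians was 2.78 (lower quartile 1.89, 23 genes). A response of the sorted or feeder cells to OKSM, the vector or the culture stays open and untested.

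The GMP arrays carry different labels in the source names, the titles and the value table. If the total is a mixture of fast and slow cells, it should lie between them. Over all genes it did so for 58.5% by source names, 21.6% by titles and 19.9% by value table columns read by source (by title 58.5%, fast and slow exchanged). Of the genes called against both others, it lay outside them in 27 of 105, 220 of 221 and 449 of 450. Under every labelling some genes thus lie outside such a mixture, so the test does not settle the labels. The share outside was smallest, 27 of 105, where the arrays named total by source were taken as the total. By the source names the total also lacked the Jchain signal of the slow group, at least 52.4-fold higher there. Which labels are right stays open. No biological explanation was tested. The names of the scanner files add a dye label, high on the arrays named slow by source, low on those named fast and none on those named total.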
